A study of Mus musculus with 2 samples.

How the data were processed

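Poly(A)+ RNA of cultured mouse embryonic fibroblasts was sequenced as single-end reads on an Illumina HiSeq, with 1 library from cells labelled Adar2-WT and 1 library from cells labelled Adar2-KO. The labels give the TruSeq or the Nextera kit for library construction without saying which library had which. Each library was put in its group by the title and genotype in the labels. The submitters' processing notes name STAR 2.4.0d, SAMtools and the mouse genome build mm9, without giving the step each belongs to.

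The expression values are RPKM (reads per kilobase of gene, scaled to library size), 1 column per library in a table deposited by the authors that has the layout of GFOLD output, per the file headers. The same deposited table holds a log2 fold change, a generalized log2 fold change (the GFOLD value, shrunken toward 0 where reads are few) and an empirical FDR, per the file headers. The empirical FDR stood at 1 in every row and was not used. The gene annotation, the counting rule, the use of strand and the treatment of duplicate reads are not given in the sources used here. Reads of near-identical genes and of overlapping or antisense genes can therefore be split or shared in ways that cannot be followed, which concerns Rps4l with Rps4x, the histone genes, the H2 genes, the Ifi20x genes, Tgtp1 with Tgtp2, and Xist with Tsix.

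The editing files deposited by the authors list 1 site per line with its mm9 position, gene, strand and annotated region. Per the file headers they give the count of reads over the site, the count of reads with the mismatch, and the editing level as a fraction, which equals the ratio of the 2 counts after rounding. The caller and its filters are not given in the sources used here. Every listed site has at least 2 reads with the mismatch, and every one is an A on the plus strand or a T on the minus strand, the base changes that A-to-I editing gives. A site missing from a list is not thereby shown to be unedited, and its depth in that library is not given.

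Depth was recovered from the expression table. The authors' log2 fold change of a gene at 0 in 1 library is that of its reads plus 1, and these values gave whole reads. Together with the RPKM values they gave a total of 9446911 reads behind the RPKM values of the WT-labelled library and 9546998 behind those of the KO-labelled library. At these totals the implied lengths of 1045 genes lay a mean of 0.0014 bases from whole numbers. A single pair of whole read numbers gave back the 6 printed digits of 16792 of 17981 genes above 0 (93.4%), with a tolerance of 0.1 reads for genes at 0 in 1 library. The remaining genes had several solutions (1187) or none within the lengths searched (2). RPKM stayed the measurement. The recovered reads served to give the reads behind a value and an exact 95% (Clopper-Pearson, conditional on the sum) interval of the log2 ratio of reads per total, which covers counting error only. Values have a ceiling: no gene exceeded 1.01 reads per base in the WT-labelled library or 1.19 in the KO-labelled library, the highest RPKM values were 107.0 and 124.3, and no listed site had more than 107 reads. Differences between abundant genes can be compressed by whatever sets that ceiling.

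Log2 ratios are log2((KO + 1)/(WT + 1)) of the RPKM values, a scale that understates the difference of low genes. A gene was compared when its larger value was at least 1 RPKM. The design had foreseen counts with a filter of counts, and for normalized values the ratio, filter and pseudocount used here. With 1 library per genotype no p-value across genes was computed and no difference has a replicate check. For each gene list with at least 5 compared members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean RPKM in 20 bins (seed 1). The percentile describes these 2 libraries. The 29 gene lists, the named-gene rule, the tests and most of the other settings tried were fixed before the data were examined, and 3 further lists were added after.

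Editing levels were computed as percent of reads with the mismatch, with Wilson 95% intervals. Sites listed in both libraries with at least 10 reads in each were compared by Fisher's exact test on edited and unedited reads, with Benjamini-Hochberg adjustment over those sites and a threshold of 0.05. That test compares the 2 libraries, not the genotypes. Reads without molecular identifiers are not independent molecules, so all intervals cover counting error only. In levels pooled over sites, a read counts at each listed site it covers, which makes those intervals too narrow even for that.

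Named genes are Adarb1, Adar and Adarb2, the 12 genes with the largest and the 12 with the smallest log2 ratio among genes with at least 10 RPKM in a library (gene models, microRNA and snoRNA symbols left out), and the 2 highest and 2 lowest members of each list at that floor. Named sites are the 10 with the largest level difference among shared sites with at least 20 reads in both libraries, the 10 with the highest level among WT-labelled sites with at least 20 reads that the KO-labelled list lacks, all listed sites in genes of the recoding list, and the 5 genes with most sites. Other names were chosen after their values were seen.

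The alternatives tried were median centring, upper-quartile scaling, other filters, a pseudocount of 0.1, a 4-fold threshold, other read minimums, other subsets of sites and other matching of random lists. Base context around edited sites was not analysed here, since no mm9 genome was used. On simulated data made from these files, 2 of 40 unshifted lists of 20 genes fell outside the 2.5 to 97.5 percentile range, and 40 of 40 lists shifted by 1 on the log2 scale lay above it. These lists were random genes with shuffled log2 ratios, so they do not show how often a list of genes regulated together leaves the range. Of the 23 lists with a percentile that were fixed before, 11 lay outside the range. In simulated draws at the depths of the 55 tested sites, the Fisher test passed 67.4% of sites set to 0.25 of their level and 1.04% of unchanged sites. Of 600 simulated genes, 87.5% had a single whole-read solution, and 100% of those solutions were right. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.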

Results

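Mouse embryonic fibroblasts, connective tissue cells grown in culture from embryos, were compared between a culture labelled as Adar2 wild-type and a culture labelled as lacking Adar2. Adar2, listed under the symbol Adarb1, encodes an enzyme that deaminates adenosine to inosine in double-stranded RNA, and inosine is read as G in sequencing. Poly(A)+ RNA-seq gave gene expression as RPKM for 24015 genes and a list of edited sites for each library. There was 1 library per genotype, so no difference described here can be set against the spread between cultures, and all intervals cover counting error only. The expression values rested on 9446911 reads in the WT-labelled library and 9546998 in the KO-labelled library. The edited sites had a median depth of 15 reads (range 2 to 107) in the WT-labelled library and 14 reads (range 2 to 79) in the KO-labelled library.

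The transcript of the targeted gene was read first. Adarb1 was higher, not lower, in the library labelled Adar2-KO: 25.8 RPKM (1633 reads) against 18.4 RPKM (1155 reads) in the library labelled Adar2-WT. The log2 ratio of reads had a 95% interval of 0.37 to 0.59, and the authors' deposited table gives Adarb1 a GFOLD value of 0.41. The labels do not name the deleted exon, and a value over the whole gene cannot check a deletion of part of it. The libraries are therefore called KO-labelled and WT-labelled throughout, and every direction below rests on those labels. Adar, which encodes the other active editing enzyme, ADAR1, was lower in the KO-labelled library, at 18.7 against 28.0 RPKM (interval of the log2 reads ratio -0.69 to -0.47). Adarb2, a family member known mainly from brain, had 2 reads in the WT-labelled library and 0 in the KO-labelled library. In the ADAR family list, the tRNA deaminase genes Adat1 (9.65 and 12.9 RPKM), Adat2 (9.33 and 14.3 RPKM) and Adat3 (14.2 and 20.8 RPKM) had the higher value in the KO-labelled library, and the median log2 ratio of the 5 compared members was 0.46 (percentile 98.6 of matched random lists).

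RNA editing was far lower in the KO-labelled library. Its list held 110 sites, against 654 in the WT-labelled library, and 75 sites were in both. At the shared sites, 55.0% of reads, counted at each site they cover, carried the edited base in the WT-labelled library (Wilson 95% interval 52.7 to 57.3, 979 of 1780 reads). In the KO-labelled library the share was 17.1% (15.5 to 18.9, 334 of 1949 reads). A read can thus count at several neighbouring sites, so both intervals are too narrow even as counting error. As means of site levels, the WT-labelled and KO-labelled libraries had 60.0% and 26.5%. At 5 shared sites the level was 95% or more in both libraries, and whether their mismatch comes from editing or from the genome was not tested. Without sites at 95% or more in either library, the pooled levels were 51.1% and 12.8%. A shared site is listed, and so has at least 2 edited reads, in both libraries. The 579 sites listed only in the WT-labelled library are left out. KO-labelled levels at shared sites can therefore overstate those at WT-labelled sites as a whole. Of the 55 shared sites with at least 10 reads in both libraries, 52 had a lower level in the KO-labelled library, 2 a higher level and 1 the same level. The difference passed Fisher's exact test (two-sided, Benjamini-Hochberg adjusted) at 33 sites, all lower in the KO-labelled library, and the median level over the 55 sites was 58.3% against 13.0%. No site passed in the other direction, adjusted or unadjusted; 36 sites had an unadjusted p under 0.05. The test compares these 2 libraries, not the genotypes. The 55 tested sites lay in 35 genes or classes, with all intergenic sites as 1 class, so neighbouring sites are not independent.

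**Figure D1:**
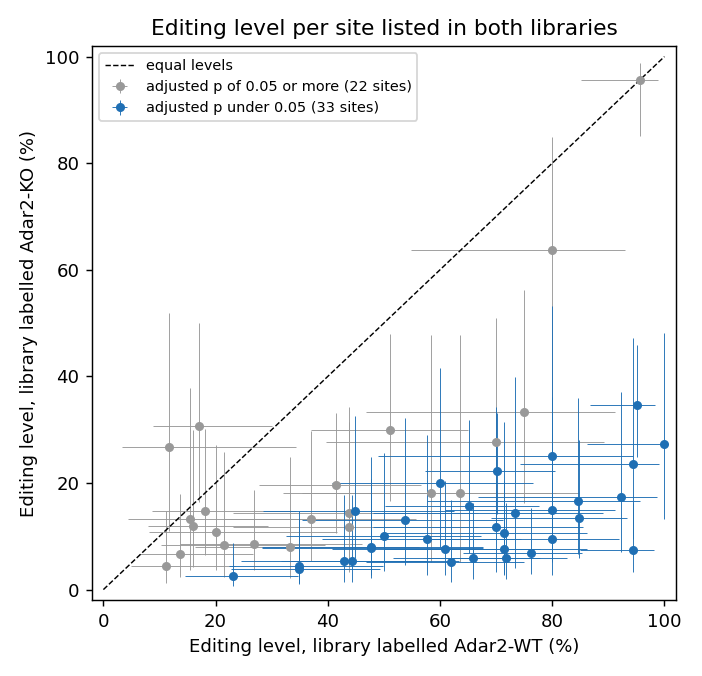
Editing level in percent of reads at each of the 55 sites with at least 10 reads in both libraries, WT-labelled on the x axis and KO-labelled on the y axis, with Wilson 95% intervals as bars. The 33 sites with an adjusted p under 0.05 (blue) all lie below the dashed line of equal levels.

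The 3′ untranslated region (UTR) of Rpa1, which encodes the large subunit of replication protein A, held the largest difference among well-covered shared sites. On chromosome 11 (mm9), position 75114080 was edited in 94.4% of 54 reads in the WT-labelled library and in 7.46% of 67 reads in the KO-labelled library (adjusted p = 9.59e-23, Fisher's exact test). Position 75114095 had 76.3% and 6.94%. Position 75114517 kept more editing, with 95.2% of 62 reads and 34.7% of 75 reads (adjusted p = 4.53e-13, Fisher's exact test). Trove2, encoding the Ro60 RNA-binding protein, was edited at chromosome 1 position 145602508 in its 3′ UTR in all 24 reads of the WT-labelled library and in 27.3% of 22 reads of the KO-labelled library.

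Sites of the same kind lay in the 3′ UTRs of an RNA-binding repressor, a phosphatase subunit and an exocyst subunit. Levels were 66.0% and 6.0% in Pum2 (chromosome 12, 8757075), 71.7% and 6.0% in Ankrd28 (chromosome 14, 32513849), and 80.0% and 15.0% in Exoc8 (chromosome 8, 127418084), the WT-labelled library given first. The noncoding transcript uc012aji.1 on chromosome 17 (6122608) had 71.4% and 7.69%. All of these sites passed the adjusted Fisher test. Of the 40 tested sites in 3′ UTRs 25 passed, as did 24 of the 42 in repeats and 9 of the 13 outside repeats.

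Recoding sites, where editing alters the encoded amino acid, were among the shared sites and among those listed in 1 library. The isoleucine-to-valine site of Cog3, a Golgi tethering factor, on chromosome 14 (76119526) was edited in 84.8% of 33 reads in the WT-labelled library (interval 69.1 to 93.3) and in 13.5% of 37 reads in the KO-labelled library (5.91 to 28.0; adjusted p = 1.50e-08, Fisher's exact test). The tyrosine-to-cysteine site of Blcap on chromosome 2 (157383885) stood at 18.2% of 33 reads (8.61 to 34.4) and 14.7% of 34 reads (6.45 to 30.1), a difference within counting error. A glutamine-to-arginine site of Blcap (157383876) was listed only in the KO-labelled library, at 10.3% of 39 reads. The only amino acid change outside the recoding list was a glutamine-to-arginine site of uc008kxa.2 on chromosome 2 (91776930), at 11.8% of 17 reads and 26.7% of 15 reads. It and a 3′ UTR site of BC048355 on chromosome 17 (46636327; 17.0% of 47 reads and 30.8% of 26 reads) were the 2 tested sites with a higher level in the KO-labelled library, and neither passed.

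Further sites in genes of the recoding list were listed in the WT-labelled library only. Among them were the lysine-to-arginine site of Igfbp7 on chromosome 5 (77836756; 26.7% of 86 reads) and its arginine-to-glycine site (77836808; 34.2% of 79 reads), and the glutamine-to-arginine site of the actin crosslinker Flna on chromosome X (71472201; 8.41% of 107 reads). Azin1, an inhibitor of antizyme, had its serine-to-glycine site on chromosome 15 (38421367) at 13.8% of 58 reads, beside a synonymous site (38421368) at 6.90%. Dact3 had an arginine-to-glycine site on chromosome 7 (17470696) in 8 of 16 reads. An intronic site was listed in Flna (71471989; 6.45% of 31 reads). Igfbp7, Flna and Azin1 remained expressed in the KO-labelled library (77.5, 91.4 and 46.0 RPKM). The 25 genes of the recoding list had 16 compared members with a median log2 ratio of 0.04 (percentile 76.8). Of these members, 2 were at least 2-fold higher and 2 at least 2-fold lower in the KO-labelled library, and 12 lay within 2-fold. Among members with at least 10 RPKM in a library, the ends were Dact3 (36.2 and 18.1 RPKM) and Igfbp7 (log2 ratio -0.21), lower in the KO-labelled library, and Mfn1 (16.9 and 19.3 RPKM) and Ube2o (25.5 and 34.9 RPKM), higher there.

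Most WT-labelled sites, 579 of 654, were not in the KO-labelled list. Among those with at least 20 reads, the highest levels were in the 3′ UTRs of Rbm8a, an exon junction protein (chromosome 3, 96436383; 96.3% of 27 reads), Mmgt1 (chromosome X, 53840820; 19 of 20 reads), Exoc8 (127417779; 88.9% of 27 reads) and the ubiquitin ligase gene Rnf168 (chromosome 16, 32300374; 85.0% of 20 reads). Next came 2010106G01Rik on chromosome 2 (126717200; 85.0% of 20 reads, and 126717253; 76.2% of 21 reads), Rpa1 (75114079; 79.6% of 54 reads), Psma3 (chromosome 12, 72095616; 15 of 20 reads), Dnajc1 (chromosome 2, 18137001; 72.7% of 22 reads) and 2900026A02Rik (chromosome 5, 113516854; 71.4% of 49 reads). RPKM values of those genes that the expression table holds were close in both libraries, as in Rnf168 (28.5 and 28.6) and Dnajc1 (21.5 and 24.4). No listed site has fewer than 2 edited reads, and a missing site is not thereby shown to be unedited.

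Most genes with sites had few of them, and 5 had more than 10. Car5b, a mitochondrial carbonic anhydrase gene, had 31 sites in its 3′ UTR on chromosome X (160414858 to 160416792) in the WT-labelled library and 1 in the KO-labelled library. C330018D20Rik had 19 and 4 sites (chromosome 18, 57116138 to 57116711), Rpa1 17 and 5 (chromosome 11, 75114062 to 75114542), Dnajc1 12 and 0 (chromosome 2, 18136274 to 18137021), and uc012aji.1 11 and 6 (chromosome 17, 6122608 to 6123086). In the WT-labelled library 63.5% of sites were in 3′ UTRs, 18.8% were intergenic, 12.2% intronic and 3.82% in noncoding RNA, and 80.6% lay in annotated repeats. In the KO-labelled library 48.2% were in 3′ UTRs and 26.4% intronic. Of the 35 sites listed only there, 28 had under 10 reads and 23 were intronic. An exception, chosen after its values were seen, was a 3′ UTR site of the polycystin gene Pkd2 (chromosome 5, 104933377), edited in 44.8% of 58 reads.

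Genes with edited sites showed no shift as a group in either direction. For the 174 compared genes with a site in the WT-labelled library the median log2 ratio was 0.00 (0.0041 before rounding; percentile 35.5), and 167 of them lay within 2-fold. The subset with 3′ UTR sites (127 genes, median 0.0033, percentile 34.4), the 42 genes with intronic sites (median 0.02, percentile 63.7) and the 6 genes with coding sites (median -0.0066, percentile 48.9) also lay inside the range of matched random lists. Factors of mRNA decay and stability, among them the decapping and deadenylation enzymes, had 0 of 29 members 2-fold apart (median 0.07, percentile 91.5). Their ends were Zfp36l2 (78.3 and 69.2 RPKM) and Zfp36 (47.3 and 42.0 RPKM), and Zfp36l1 (39.2 and 57.2 RPKM) and Pan2 (7.49 and 14.6 RPKM).

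Expression of many other genes differed between the libraries. Of 13867 genes with at least 1 RPKM in a library, 613 (4.42%) were at least 2-fold higher and 1035 (7.46%) at least 2-fold lower in the KO-labelled library on the scale of RPKM + 1. By the authors' deposited table, 483 genes had a GFOLD value of at least 1 and 853 a value of at most -1. Interferon-induced genes were 3 of the 12 lowest. No difference has a replicate check. In the lists below, members named as lowest or highest are those with at least 10 RPKM in a library.

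At the lower end, Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf, had 57.7 RPKM (619 reads) in the WT-labelled library and 0.092 RPKM (1 read) in the KO-labelled library (95% interval of the log2 reads ratio -14.59 to -6.81). The choline transporter gene Slc5a7 (51.4 RPKM, 2513 reads), the ribosomal protein paralog Rps4l (41.2 RPKM, 366 reads), the homeobox gene Meox2 (36.7 RPKM, 813 reads) and Tbx4 (34.7 RPKM, 1069 reads), a transcription factor of the hindlimb, were listed at 0 in the KO-labelled library. The cartilage collagen gene Col2a1 had 48.0 and 0.571 RPKM, Rcan2 35.0 and 0.163 RPKM, Mab21l2 25.6 and 0.039 RPKM and the mast cell and basophil protease gene Mcpt8 38.0 and 0.624 RPKM. The remaining 3 of the lowest 12 were the interferon-induced genes Ifi44 (42.5 and 0.252 RPKM), Oasl2 (33.7 and 0.301 RPKM) and Iigp1 (29.8 and 0.235 RPKM).

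At the upper end, Ifi202b, an interferon-inducible gene of the HIN-200 family, had 0.059 RPKM (1 read) in the WT-labelled library and 54.4 RPKM (933 reads) in the KO-labelled library (interval 7.37 to 15.16). The homeobox gene Hoxb9 had 0.039 and 32.5 RPKM, and Emx2, another homeobox gene, was listed at 0 in the WT-labelled library and at 20.9 RPKM (519 reads) in the KO-labelled library. The transcription factor genes Foxf1 (0.218 and 23.5 RPKM) and Tfap2b (0.033 and 16.5 RPKM) were also among the highest 12. The imprinted growth inhibitor gene Grb10 had 1.54 and 67.2 RPKM (interval 5.12 to 5.80). The others were Arhgef5 (0.059 and 27.5 RPKM), Slc16a13 (0.042 and 26.1 RPKM), the creatine synthesis gene Gatm (0.359 and 27.2 RPKM), Rhbdf2 (0.135 and 20.7 RPKM), the cholecystokinin gene Cck (0.248 and 22.4 RPKM) and Apol10b (0.640 and 26.8 RPKM).

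**Figure D2:**
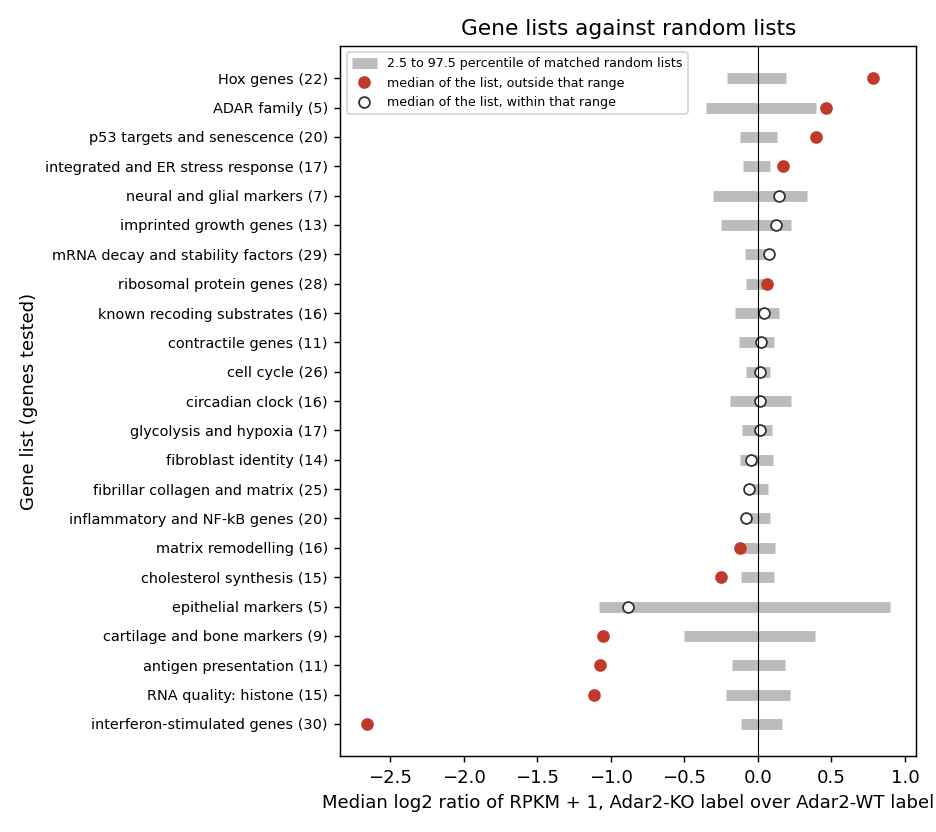
Median log2 ratio of RPKM + 1 (KO-labelled over WT-labelled) of each gene list fixed before the data were examined that had at least 5 compared genes. The number of genes is in brackets, and the central 95% range of 10000 matched random lists is in grey. Interferon-stimulated genes lie lowest at -2.66 and Hox genes highest at 0.78.

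Interferon-stimulated genes, induced by type I interferon and double-stranded RNA, were lower in the KO-labelled library as a group. All 30 members were lower there and 28 were at least 2-fold lower. Their median log2 ratio was -2.66, below all 10000 matched random lists (95% range -0.12 to 0.16), and their mean was 28.7 RPKM in the WT-labelled and 6.22 RPKM in the KO-labelled library. Ifit1 had 42.9 and 0.874 RPKM, the master regulator gene Irf7 39.1 and 2.08 RPKM, the double-stranded RNA sensor gene Ifih1 21.1 and 0.418 RPKM and the ubiquitin-like modifier gene Isg15 57.5 and 7.07 RPKM. The least different members were Stat2 (27.2 and 16.2 RPKM) and Eif2ak2 (53.1 and 33.8 RPKM), which encodes the kinase PKR. Antigen presentation genes were lower with them, all 11 in direction and 6 by at least 2-fold (median -1.07, below all random lists). The immunoproteasome genes Psmb8 (19.4 and 0.771 RPKM) and Psmb9 (18.0 and 1.95 RPKM) differed most, Tapbp (59.4 and 46.5 RPKM) and B2m (73.9 and 58.5 RPKM) least. Psmb8 and Tap1 belong to both lists.

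**Figure D3:**
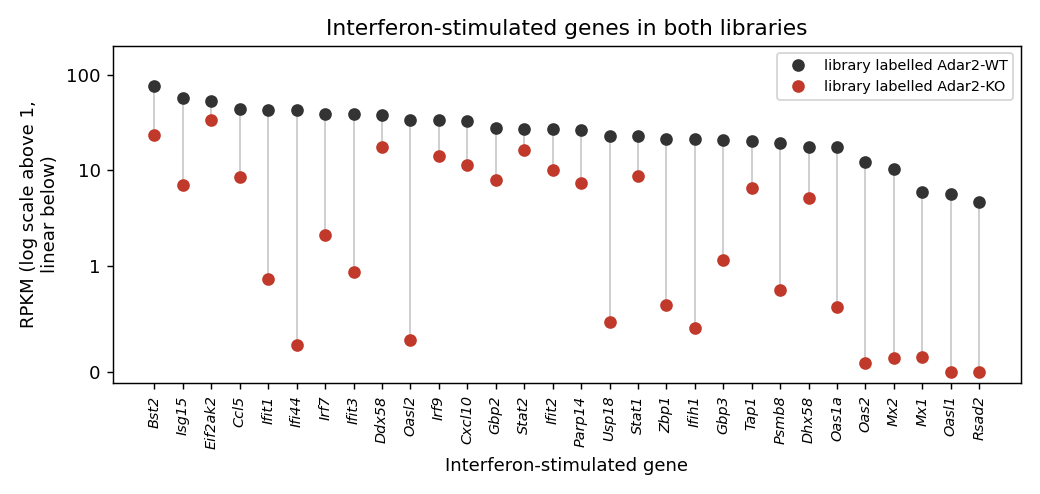
RPKM of the 30 interferon-stimulated genes in the WT-labelled library (black) and the KO-labelled library (red), ordered by the WT-labelled value, on an axis that is logarithmic above 1 and linear below. Every gene is lower in the KO-labelled library, by least at Eif2ak2 (53.1 and 33.8 RPKM) and by most at Ifi44 (42.5 and 0.252 RPKM).

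Replication-dependent histone genes, whose transcripts normally lack a poly(A) tail and whose level in poly(A)+ libraries can follow RNA selection, were also lower. All 15 were lower in the KO-labelled library and 8 were at least 2-fold lower (median -1.11, below all random lists). Hist2h3b (25.7 and 5.43 RPKM) and Hist1h1b (11.6 and 2.77 RPKM) differed most, Hist2h2aa1 (31.6 and 20.3 RPKM) and Hist1h1c (log2 ratio -0.41) least. Cell cycle genes were close, with 0 of 26 members 2-fold apart (median 0.02, percentile 66.9). Their ends were Ccne1 (35.4 and 24.1 RPKM) and Rrm2 (42.2 and 31.2 RPKM), and Aurkb (27.5 and 31.5 RPKM) and Birc5 (17.9 and 23.9 RPKM).

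Hox genes, which carry the positional identity of fibroblasts, were higher in the KO-labelled library as a group (median 0.78 over 22 compared genes, above all random lists), with 9 at least 2-fold higher and 1 at least 2-fold lower. Hoxb8 was listed at 0 in the WT-labelled library and at 10.5 RPKM (264 reads) in the KO-labelled library, and Hoxb3, Hoxb4, Hoxb5 and Hoxb6 were likewise listed at 0 in the WT-labelled library, with 7.04, 5.76, 3.65 and 9.19 RPKM in the KO-labelled library. Hoxd13 was close (64.8 and 55.1 RPKM), and Hoxa13 (28.7 and 13.1 RPKM) was the 1 member at least 2-fold lower. Imprinted growth genes went both ways (3 higher and 3 lower by 2-fold, of 13; median 0.12, percentile 88.1). The noncoding RNA H19 (68.5 and 6.85 RPKM) and Mest (48.2 and 5.28 RPKM) were lower in the KO-labelled library, Grb10 was higher, and Igf2r was close (46.5 and 50.7 RPKM). With at least 5 RPKM in a library required, the median of the imprinted list turned to -0.42 and lay below the random range (percentile 0.09).

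Targets of p53 and senescence genes were mostly higher in the KO-labelled library, 18 of 20 in direction with 2 at least 2-fold higher and 2 at least 2-fold lower (median 0.39, above all random lists). The apoptosis-linked genes Trp53inp1 (4.64 and 23.4 RPKM) and Perp (0.613 and 20.6 RPKM) were highest, and Cdkn1a, encoding the cell cycle inhibitor p21, had 30.1 and 59.3 RPKM. Both 2-fold lower members, Cdkn2a and Cdkn2b (49.4 and 16.3 RPKM), are neighbours in the Ink4 locus. Genes of the integrated and ER stress response were slightly higher (median 0.17, percentile 99.98) with 0 of 17 apart by 2-fold, between Sdf2l1 (42.9 and 30.7 RPKM) or Dnajb9 (34.5 and 27.0 RPKM) and Slc7a11 (13.8 and 24.9 RPKM) or Sesn2 (22.5 and 41.7 RPKM). Cholesterol synthesis genes were slightly lower (median -0.25, percentile 0.01; 13 of 15 in direction, 0 by 2-fold), with Mvd (49.2 and 30.6 RPKM) and Idi1 (61.7 and 43.2 RPKM) lowest and Srebf2 (42.4 and 46.3 RPKM) and Sqle (48.7 and 53.7 RPKM) highest.

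Cartilage and bone markers were lower in the KO-labelled library (median -1.06, percentile 0.105; 5 of 9 by 2-fold), led by Col2a1, but Spp1 (76.7 and 68.4 RPKM), Runx2 (28.5 and 27.0 RPKM) and Sox9 (12.8 and 14.5 RPKM) were close. With at least 5 RPKM in a library required, the median was -0.16 and lay inside the random range (percentile 10.7). Matrix remodelling genes were split (median -0.12, percentile 2.35, 3 lower and 1 higher of 16 by 2-fold). The protease inhibitor gene Serpine2 had 71.8 and 3.47 RPKM and the collagenase gene Mmp13 33.0 and 9.36 RPKM, while Mmp2 had 18.8 and 55.9 RPKM and Mmp11 33.4 and 53.3 RPKM.

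Fibroblast genes showed no shift as a group, but some members lay far apart. Fibrillar collagen and matrix genes had 23 of 25 members within 2-fold (median -0.06, percentile 11.1), with Dcn (29.7 and 12.3 RPKM) and Tnc (69.8 and 40.5 RPKM) lowest and Fbn1 (67.8 and 77.6 RPKM) and Postn (21.9 and 41.2 RPKM) highest. Fibroblast identity genes had a median of -0.04 (percentile 26.9) over members that went far in both directions, with a median absolute log2 ratio of 0.38, above all matched random lists: Meox2 and Twist2 (53.8 and 31.9 RPKM) were lower, Cd34 (20.6 and 41.6 RPKM) and the surface glycoprotein gene Thy1 (9.40 and 72.1 RPKM) higher. Contractile genes had a median of 0.02 (percentile 71.2), with Cnn1 (31.9 and 19.9 RPKM) and Csrp1 (62.1 and 58.6 RPKM) lowest and Mylk (6.72 and 16.4 RPKM) and Actg2 (15.5 and 45.4 RPKM) highest.

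Inflammatory and NF-kB genes had a median of -0.08 (percentile 7.70) with 5 of 20 at least 2-fold lower, among them Mmp13 and Lcn2 (81.5 and 34.1 RPKM), while Ccl2 (56.7 and 65.6 RPKM) and Ptgs2 (43.9 and 56.1 RPKM) were slightly higher. Glycolysis and hypoxia genes had a median of 0.02 (percentile 68.4) with 0 of 17 apart by 2-fold, from Pfkp (36.4 and 30.8 RPKM) and Ankrd37 (21.7 and 19.2 RPKM) to Ndrg1 (44.9 and 64.0 RPKM) and Egln3 (11.7 and 23.2 RPKM). Clock genes had a median of 0.02 (percentile 47.5), with 2 of 16 at least 2-fold higher, Npas2 (1.98 and 7.24 RPKM) and Hlf (0.243 and 4.12 RPKM), and 1 at least 2-fold lower, Dbp (12.8 and 5.81 RPKM). Cry2 (20.8 and 11.5 RPKM), Nr1d1 (25.9 and 29.4 RPKM) and Per1 (9.91 and 11.4 RPKM) lay within 2-fold. Ribosomal protein genes, a reference for scaling, had a median of 0.06 (percentile 98.1) with 0 of 28 apart by 2-fold, from Rps7 (46.4 and 39.5 RPKM) and Rplp2 (31.0 and 26.4 RPKM) to Rplp0 (50.7 and 61.5 RPKM) and Rpl19 (40.9 and 51.0 RPKM). The ceiling on values can compress differences in lists of abundant genes such as this list and the fibrillar collagen and matrix list.

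Markers of other cell types were mostly near 0 in both libraries. The leukocyte gene Ptprc had 4 and 0 reads, Tyrobp, Emr1, Myod1 and Sox10 were listed at 0 in both, and the endothelial genes Pecam1 and Cdh5 had 15 and 6 reads in the WT-labelled library and 3 and 1 in the KO-labelled library. Of the neural and glial markers (median 0.14, percentile 80.7, 7 compared), Sox2 had 24.2 and 0.171 RPKM, Map2 32.7 and 15.8 RPKM, Stmn2 38.6 and 42.7 RPKM and Nes 14.3 and 38.4 RPKM. With at least 5 RPKM required, the median of that list turned to -0.33 and lay below the random range (percentile 1.0). Among epithelial markers (median -0.88, percentile 6.76, 5 compared) Krt19 had 59.4 and 18.8 RPKM. Fewer than 5 members were compared in the endothelial (3), macrophage and blood (4), skeletal muscle (2) and adipocyte (4) lists. Above 10 RPKM in a library these held Cd14 (19.7 and 23.7 RPKM), Cebpa (18.5 and 3.53 RPKM) and Fabp4 (39.6 and 42.5 RPKM). Xist, the noncoding RNA of X inactivation, had 39.0 and 55.0 RPKM and its antisense partner Tsix 10.2 and 19.6 RPKM, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in both libraries. The table held 0 of the 20 mitochondrial symbols searched.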

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

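The GFOLD count, the count over genes up to 0.5 reads per base and the set of edited genes without interferon-stimulated genes were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because there was 1 library per genotype and the labels carry no replicate numbers that match cultures. Base context was not run, so its alternative was not run either. Median centring and upper-quartile scaling shifted the log2 ratios by 0.01 or less. A pseudocount of 0.1, the GFOLD value and the limit on reads per base left both counts of 2-fold genes within 1.5 times. Requiring 5 RPKM in a library gave 353 higher and 659 lower genes, fewer genes being compared, and a 4-fold threshold 146 and 337. Requiring 20 reads left 253 and 44 edited sites, and a level of at least 10% and under 95% left 73 in the KO-labelled list. With a minimum of 5 reads, 1 shared site passed as higher in the KO-labelled library, an intergenic site on chromosome 13 (62915954) edited in 3 of 14 and 6 of 6 reads. Pooled levels were 60.0% and 26.5% as means of site levels and 51.1% and 12.8% without sites at 95% or more in either library. Of WT-labelled sites with at least 20 reads, 84.2% were missing from the KO-labelled list, against 88.5% of all. Of 68 alternatives for list medians, 23 were median centring, which shifts every gene alike and could not change a percentile. Of all 68, 63 moved by no more than 0.5 times the width of the random range and 0 reversed a list outside that range. The others were a pseudocount of 0.1 for interferon-stimulated genes (-4.10) and Hox genes (0.99), and the 5 RPKM filter for imprinted growth genes (-0.42), neural and glial markers (-0.33) and cartilage and bone markers (-0.16); the cause was not tested. Edited genes stayed inside the random range under the other matchings (percentiles 18.6 and 54.9) and with at least 2 sites per gene required (78 genes, percentile 60.8), and none of them is on the interferon list.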

Other observations

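All tests of explanations below were chosen after the results were seen. Families related to the interferon response differed within themselves; their lists were put together after the data were seen. Of 15 compared interferon-inducible GTPase genes, which act against intracellular pathogens, 11 were at least 2-fold lower in the KO-labelled library (median log2 ratio -1.67), among them Irgm2 (31.1 and 1.01 RPKM, WT-labelled first), Igtp (29.7 and 0.932 RPKM) and Gvin1 (33.0 and 4.73 RPKM). Gbp9 went the other way (0.379 and 4.90 RPKM) and Irgm1 was close (47.7 and 36.9 RPKM). The HIN-200 family of DNA-binding interferon-inducible proteins was split: Ifi205 (39.8 and 0.909 RPKM) and Mnda (64.4 and 23.9 RPKM) were lower, Ifi202b (0.059 and 54.4 RPKM) and Aim2 (5.17 and 12.1 RPKM) higher. These genes are close paralogs, and how their shared reads were counted is not given.

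Among 34 compared transcription factors with regional roles in the embryo, also listed after the data were seen, 14 were at least 2-fold higher and 6 at least 2-fold lower in the KO-labelled library. Sall1 (21.9 RPKM), Six2 (20.8 RPKM) and Tbx4 were listed at 0 in the KO-labelled library, and Lhx9 had 20.3 and 2.0 RPKM. In the other direction, Lhx8 (11.7 RPKM) and Hand2 (3.37 RPKM) were listed at 0 in the WT-labelled library, and Tbx3 (0.503 and 13.1 RPKM), Nr2f1 (0.871 and 22.0 RPKM), Zic2 (0.071 and 16.3 RPKM) and Gata6 (2.72 and 11.9 RPKM) were higher in the KO-labelled library. The hindlimb factor Pitx1 was high in both (46.0 and 39.6 RPKM), and the forelimb factor Tbx5 had 0 and 3 reads. By reads per base, the share of genes 2-fold apart was 8.35% (489 of 5859) at 0.1 to 0.3 and 3.20% (123 of 3846) at 0.3 to 0.6. It was 4.80% (22 of 458) at 0.6 to 0.8 and 0 of 59 at 0.8 or more, which is not a steady decrease. The standard deviation of the log2 ratio in these bins was 0.74, 0.53, 0.56 and 0.13. Genes nearest the ceiling thus varied least, and compression there may lie behind this and was not tested.

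Editing was lower in the KO-labelled library although Adarb1 was higher there. Fewer reads over the sites argue poorly for this: in genes at least as high in the KO-labelled library, 44 of 57 WT-labelled sites with at least 10 edited reads (77.2%) were missing from the KO-labelled list. The 57 sites came from 20 genes, 14 of them from the same gene, and in 16 of the 20 genes (80.0%, Wilson 95% interval 58.4 to 91.9) most such sites were missing. Lower Adar (log2 ratio -0.56) is confounded with the label in this design and cannot be told apart from loss of ADAR2 as a source of the difference. Loss of ADAR2, the difference the labels name, and swapped labels both stay open. Lower editing at all 33 shared sites that passed runs the way the labels say if ADAR2 edits them. Higher Adarb1 runs the other way, but a value over the whole gene cannot check a deletion of part of it.

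Interferon-stimulated transcripts were lower in the KO-labelled library. Leukocyte RNA in the WT-labelled library is argued against as far as 4 genes go, since Ptprc, Tyrobp, Fcer1g and Aif1 reached at most 0.643 RPKM there. Of the macrophage and blood list, 4 other members were compared. In the KO-labelled library 2 of them were lower, 1 by at least 2-fold, and 2 higher, among these Cd14 (19.7 and 23.7 RPKM). The mast cell and basophil gene Mcpt8 (38.0 and 0.624 RPKM) went with the interferon genes, while Cpa3, Ms4a2 and Fcer1a, other genes of those cells, were listed at 0 in both libraries. Random sets of genes outside the list with the same WT-labelled RPKM had a median log2 ratio of -0.0060 (95% range -0.11 to 0.10). They were drawn from 10371 of the 13867 compared genes. Over all compared genes, values scaled to library size had a median ratio near 0 (0.0053). A general loss of transcripts of that abundance could hardly show in such sets, so they do not decide the question. A difference in interferon signalling between the cultures, whether from genotype, culture or embryo of origin, may lie behind the pattern and was not tested.

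Regional transcription factors stood among the genes furthest apart. A candidate explanation is that the 2 cultures came from different body regions or lineages. Of 22 compared Hox genes 10 were at least 2-fold apart, but this was known before the explanation was raised, and 6 of the 10 are neighbours in the Hoxb cluster, so it does not support the explanation on its own. With 1 library per genotype, origin and genotype cannot be told apart, and this also bears on the other expression differences.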
